A study of Rattus norvegicus with 6 samples.

How the data were processed

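The data are 1 table of expression values for 6 arrays, each hybridised with a pool of liver RNA from 5 rats (1500 ng per rat), 30 rats in all. Per the labels' protocols, total RNA was extracted with TRIzol, the integrity number of accepted RNA was at least 7.0, 100 ng of RNA was labelled, and the arrays were Affymetrix whole-transcript arrays. The rats had their diets for 33 to 37 days. The labels' source fields call the animals mice, whereas the organism field and the growth protocol give rat, and they are taken as rats here. The deposited values were summarised per probe set by RMA (robust multi-array average), per the submitters' processing notes, and are on the log2 scale, as their range of 2.40 to 13.92 shows. The version and settings of RMA are not given in the sources used here. The composition of the diets is not used here.

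The table has 29214 probe sets. Gene names came from the platform annotation, which listed 15633 probe sets, of which 15310 had 1 gene symbol and 323 several, and 13581 were not listed and are unnamed here. Of the named ones, 15279 matched the RefSeq gene table by Entrez number, and 0 symbols changed. The named probe sets covered 14506 distinct symbols. Where a symbol had several probe sets, the one with the highest mean over all arrays was used, and no gene was named from a probe set with several symbols. The deposited values name no genome build for probe sets, so no coordinates are given. Probe sets whose mean over the 6 arrays lay above the 30th percentile, log2 5.14, were tested, which left 20450, of which 11421 stood for a named gene each and 8356 were unnamed. The arrays' pairwise Pearson correlations lay between 0.9949 and 0.9964, and no array pair was identical.

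The main model was fitted with limma 3.58.1 in R 4.3.3 on the deposited log2 values of all 6 arrays, with terms for protein level and background and equal weights. It leaves 2 residual degrees of freedom, and eBayes gave a prior of 4.37 degrees of freedom with a prior SD of 0.094. The protein effect is the mean of 3 paired differences, and the sucrose, fat, and sucrose and fat effects are means over 2 protein levels. Error is thus how a difference varies between levels of the other factor, together with the spread between pools and arrays, and the SE given with a fold is from this fit. No diet was replicated, so p-values measure only the spread between these arrays. An interaction of protein with background leaves no residual degrees of freedom and was not tested. Calls used a Benjamini-Hochberg adjusted p under 0.05 over all probe sets tested, for each of 4 effects. Differences between 2 arrays are given as values, with counts at 1.5-fold or more.

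There were 29 gene lists, 20 of pathways and 9 of cell types or liver zones, written with 599 symbols, of which 511 genes were measured. A list was tested by camera with a preset correlation of 0.01, adjusted over the 29 lists of an effect, on members that passed the expression filter. Beside it stand camera with an estimated correlation, from 2 residual degrees of freedom, and fry. Calls "over the list alone" adjust a member's p over its own list, with no adjustment across lists. For differences between 2 arrays, the median of a list was placed among 10000 random lists of the same size matched on mean expression, and between 8 and 15 of the 29 lists lay outside the range from the 2.5th to the 97.5th percentile, depending on the difference, where 5 percent would be expected of unrelated genes. Genes of a pathway vary together, which such random lists leave out.

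The lists, the design, the filter and the rule for genes to name were set before the data were examined. The rule took, for each effect, the 12 largest rises and falls past the test with 1 direction at every level of the other factor, filled to 12 by moderated t, of which the text gives a part. From each list it took members past the test and up to 4 with the largest differences, and for each difference between 2 arrays the 5 largest in each direction.

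The model was tested on simulated data with 200 of the 20450 probe sets changed, over 10 simulations. For the protein effect, a log2 change of 0.5 was recovered in 48.4 percent, of 1 in 97.6 percent and of 2 in 100 percent, with 5.0 percent of calls wrong. For the sucrose and fat effect the shares were 14.0, 93.2 and 99.8 percent, with 5.3 percent of calls wrong. The simulated changes were the same at every level of the other factor, on noise drawn independently. So many changed probe sets also ease the adjusted threshold. The shares therefore do not give the power in the real data, where 9 and 0 probe sets passed for these effects. Simulations for a list of 20 genes shifted by 0.3 drew the noise of each gene independently. Camera with the preset correlation found the list in 10 of 10 and camera with an estimated correlation in 0 of 10. Fry found it in 3 of 10. Independent noise favours the preset correlation, whereas estimated correlations of the real lists ran from -0.035 (lipoprotein secretion) to 0.824 (red cell markers). These shares therefore do not show how camera with the preset correlation performs on lists whose genes vary together.

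Alternatives tried were no filter, a filter at the 50th percentile, eBayes with a trend and robust prior, cyclic loess and a repeated quantile normalization, array weights, an ordinary t statistic, other thresholds, no background term, each array and each background left out, and, for lists, the mean of a symbol's probe sets. Testing named genes alone, and counting concordance over the high sucrose backgrounds alone, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.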

Results

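Gene expression was measured in the livers of adult male Wistar rats kept on 1 of 6 diets, with 30 rats in all and 5 per diet. The diets crossed 2 protein levels, normal (NP) and high (HP), with 3 backgrounds. These were low fat, high sucrose (HS) and high sucrose with high fat (HS-HF). The rats ate their diet for 5 weeks, after 10 days of adaptation to the normal protein diet. They were killed 2 h after a calibrated meal of 87.6 kJ, so the livers were in a fed state. Liver RNA of the 5 rats of a diet was pooled, and each pool was hybridised to 1 whole-transcript array. The 6 arrays held 29214 probe sets, and their medians lay within 0.033 of each other on the log2 scale. The number of arrays limits the precision, because no diet has a replicate pool. The comparisons address how the protein content of a diet bears on the liver's response to sucrose and fat.

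High protein against normal protein gave 9 genes past the test, 5 higher and 4 lower. Car12, a membrane carbonic anhydrase (probe set 10911145), rose 3.66-fold (log2 1.87 ± 0.145 SE, 3 pairs of arrays, adjusted p = 0.0281). Car2, the cytosolic carbonic anhydrase (probe set 10822234), rose 1.92-fold (log2 0.94 ± 0.069 SE, adjusted p = 0.0281). Vnn1, the pantetheinase vanin 1 (probe set 10717295), fell 2.23-fold (log2 -1.15 ± 0.067 SE, adjusted p = 0.0137). Inhba, which encodes the activin A subunit (probe set 10798702), fell 2.4-fold (log2 -1.27 ± 0.078 SE, adjusted p = 0.0137). Each of the 9 genes had the same direction in the 3 backgrounds. Passing nearly requires this, because the error of the test includes how the difference varies between backgrounds.

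Spsb4, a substrate receptor of ubiquitin ligases (probe set 10919429), rose 2.95-fold (log2 1.56 ± 0.080 SE, adjusted p = 0.0135). Plppr1, a phospholipid phosphatase-related membrane protein (probe set 10869002), rose 2.34-fold (log2 1.23 ± 0.093 SE, adjusted p = 0.0281). The cell adhesion molecule Pvr (probe set 10719616) rose 1.77-fold (log2 0.82 ± 0.073 SE, adjusted p = 0.0459). The galactosyltransferase B3galt1 (probe set 10836515) fell 1.85-fold (log2 -0.88 ± 0.076 SE) and the organic anion transporter Slco1a4 (probe set 10867033) fell 1.72-fold (log2 -0.78 ± 0.068 SE), both with an adjusted p of 0.0452. Car12 differed by 1.59 on the log2 scale in the low fat background, by 2.33 with high sucrose and by 1.70 with high sucrose and high fat. Vnn1 varied less, at -1.19, -1.20 and -1.08 in the same order.

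**Figure D1:**
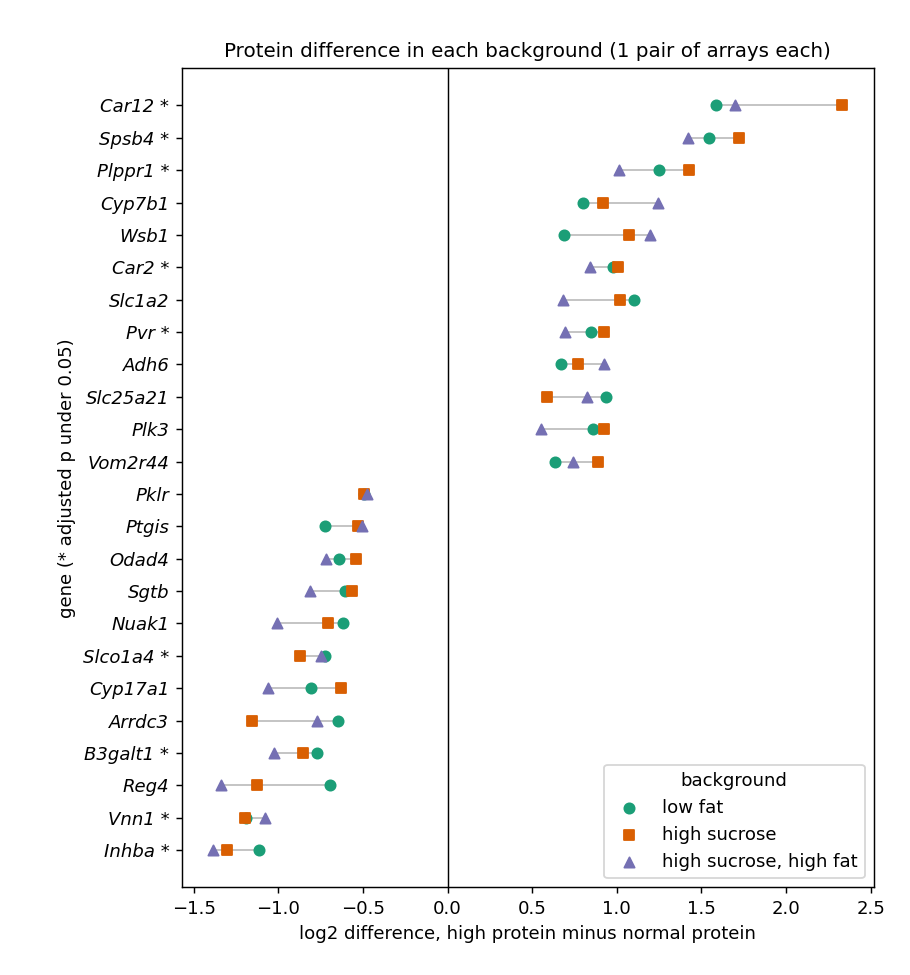
Log2 difference, high protein minus normal protein, of 24 genes on the x axis, with 1 point for each background and 1 gene per line on the y axis; an asterisk marks the 9 genes past the test, and the grey line joins the lowest and highest of the 3 differences. Each gene shown was chosen among those with 1 direction in the 3 backgrounds, and Car12 reached 2.33 in the high sucrose background.

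Next in rank, and not past the test, came Cyp7b1, the oxysterol 7-alpha-hydroxylase, at log2 0.99 ± 0.098 SE (adjusted p = 0.0594), and the glutamate transporter Slc1a2 at 0.93 ± 0.096 SE (adjusted p = 0.064). Adh6, Vom2r44, Wsb1, Slc25a21 and Plk3 had fitted differences between 0.75 and 0.99. On the lower side, the steroid 17-alpha-hydroxylase Cyp17a1 was at -0.83 ± 0.095 SE (adjusted p = 0.0775). Pklr, the liver pyruvate kinase, was at -0.49 ± 0.063 SE (adjusted p = 0.0941), with -0.49, -0.49 and -0.48 in the 3 backgrounds. Reg4, Nuak1, Arrdc3, Sgtb, Odad4 and Ptgis lay between -1.05 and -0.59, and a weaker probe set of Ptgis was at -0.22. The test was limma over 20450 probe sets, adjusted by Benjamini-Hochberg. An ordinary t statistic has 2 residual degrees of freedom here and could hardly give a call after this adjustment. An unadjusted p under 0.05 was reached by 1782 probe sets, where 1022 would be expected by chance. The count of 9 became 0 without either array of the low fat or the high sucrose background, 48 without either array of the high sucrose high fat background, and 0 with an ordinary t statistic.

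The pairs of arrays of the 3 backgrounds share no pool, so they can be set against each other. At 1.2-fold or more in all 3 backgrounds, 227 probe sets differed in 1 direction, 130 higher and 97 lower with high protein. With the sign of the low fat, the high sucrose or the high sucrose high fat difference turned, the counts were 53, 48 and 31. Unrelated differences would give the mean of the 4 patterns of signs on average, which was 89.8. At 1.5-fold the count was 33, against 0, 1 and 2 with a sign turned and a mean of 9. Across the 20450 probe sets, which are not independent replicates, the protein differences correlated at Pearson r = 0.153 (Spearman 0.074) between low fat and high sucrose. Between low fat and high sucrose high fat r was 0.119 (Spearman 0.033), and between the high sucrose backgrounds it was 0.244 (Spearman 0.217).

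**Figure D2:**
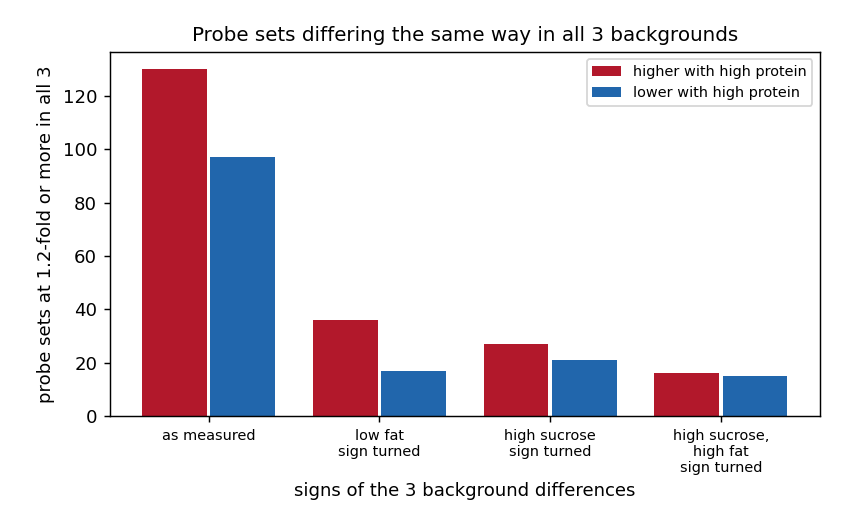
Number of probe sets (y axis) that differed 1.2-fold or more in 1 direction in all 3 backgrounds, higher (red) or lower (blue) with high protein, with the signs as measured and with the sign of 1 background turned (x axis). As measured there were 130 higher and 97 lower, against at most 36 and 21 with a sign turned.

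Within each background there was 1 array per diet, so differences are values without a test. High and normal protein differed 1.5-fold or more for 282 probe sets on low fat (151 higher), 285 on high sucrose (178 higher) and 306 on high sucrose with high fat (171 higher). On low fat the largest differences upward, after Car12 and Spsb4, were those of the DNA replication factor Mcm10 (1.5), the squalene epoxidase Sqle (1.40) and the tryptophan pathway enzyme Acmsd (1.29). Those downward were of the interferon-induced Mx2 (-1.77), the phosphate transporter Slc34a2 (-1.66), the retinaldehyde dehydrogenase Aldh1a1 (-1.64), Derl3 of endoplasmic reticulum protein disposal (-1.52) and Ly6al (-1.40). On high sucrose the circadian output gene Noct, nocturnin, stood at 1.67 and the mitochondrial carrier Slc25a25 at 1.44. On the lower side Hamp, which encodes the iron hormone hepcidin, was at -2.79 and the G protein regulator Rgs16 at -2.46. On high sucrose with high fat the neutral amino acid transporter Slc1a4 was at 2.38, the prolyl hydroxylase Egln3 at 2.33, the mitochondrial carrier Slc25a30 at 1.93 and Tor3a at 1.63. The stearoyl-CoA desaturase Scd was at -1.34 and the phenobarbital-inducible Cyp2b2 at -1.31.

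For protein, genes of fatty acid and triglyceride synthesis were lower by camera (adjusted p = 0.0104, median -0.07) and not past the test with an estimated correlation (adjusted p = 0.699). Camera with an estimated correlation found a simulated shifted list in 0 of 10, so its adjusted p, here and below, cannot decide against a list. Of 24 measured members, 0 passed the test over all genes and 6 fell past the test adjusted over the list alone. These were Acaca, acetyl-CoA carboxylase (-0.52 ± 0.093 SE), Fasn, fatty acid synthase (-0.34 ± 0.086 SE), Scd (-0.91 ± 0.174 SE), the malic enzyme Me1 (-0.57 ± 0.075 SE), Pklr and the carboxylase activator Mid1ip1 (-0.33 ± 0.065 SE). Acacb, Gpam and Fads1 were higher at an unadjusted p under 0.05. The list's median was -0.17 on low fat, 0.04 on high sucrose (14 higher, 10 lower) and -0.07 on high sucrose with high fat, the last 2 inside the range of random lists. In glycolysis and fructose use, Pklr was the member of 17 that passed over the list alone, and the list had a camera adjusted p of 0.578.

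Amino acid breakdown was higher with high protein by camera (47 members, adjusted p = 1.5e-05, adjusted p = 0.699 with an estimated correlation). Over the list alone 9 members rose and 1 fell, and 0 passed over all genes. The rises included the aminotransferases Got1 (0.69 ± 0.087 SE), Gpt (0.48 ± 0.068 SE) and Tat (0.30 ± 0.078 SE), the glycine decarboxylase Gldc (0.59 ± 0.081 SE) and the serine dehydratase Sds (0.50 ± 0.090 SE), with Hal, Cbs, Oat and Agxt. Csad, of taurine synthesis, fell (-0.62 ± 0.120 SE). The median of the list was 0.08 on low fat, 0.14 on high sucrose and 0.01 on high sucrose with high fat (24 higher, 23 lower), the last inside the range of random lists. The urea cycle list of 8 was higher (camera adjusted p = 0.0104, adjusted p = 0.699 with an estimated correlation), with argininosuccinate lyase, Asl (0.49 ± 0.070 SE), past the test over the list alone. Its median was 0.12 on low fat, 0.16 on high sucrose and 0.02 on high sucrose with high fat, the last inside that range. Gluconeogenesis was higher (17 members, camera adjusted p = 0.00574, adjusted p = 0.699 with an estimated correlation), with 5 rises and 1 fall over the list alone. Pck1, the cytosolic phosphoenolpyruvate carboxykinase (0.36 ± 0.066 SE), and the coactivator Ppargc1a (0.27 ± 0.081 SE) rose, and the pyruvate carboxylase Pc fell (-0.24 ± 0.064 SE). The medians of gluconeogenesis were 0.02, 0.12 and 0.02 in the same order, and stood outside that range on high sucrose alone. Got1, Gpt and Sds count in both the amino acid and the gluconeogenesis list. Serine synthesis (6 members, camera adjusted p = 0.917) had 0 members past either test.

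Cholesterol synthesis was higher with high protein (22 members, camera adjusted p = 1.94e-07, adjusted p = 0.699 with an estimated correlation). Over the list alone 6 members rose, among them Sqle (0.83 ± 0.174 SE), the sterol reductases Tm7sf2 (0.73 ± 0.118 SE) and Dhcr7 (0.40 ± 0.074 SE) and the SREBP retention factor Insig1 (0.69 ± 0.148 SE). Over all genes 0 passed. The list's median was 0.28 on low fat, 0.12 on high sucrose and 0.08 on high sucrose with high fat. The NP array had the lowest median deviation from the mean of the arrays, at -0.19. In bile acid synthesis and sterol transport (20 members, camera adjusted p = 0.896), Cyp7b1 rose and Nr0b2, the repressor SHP, fell (-0.58 ± 0.123 SE) over the list alone. Among PPAR alpha targets and fatty acid oxidation (33 members, camera adjusted p = 0.407), Vnn1 passed over all genes. Vnn1, the dienoyl-CoA reductase Decr1 (-0.43 ± 0.064 SE) and the hormone gene Fgf21 (-0.50 ± 0.101 SE) fell over the list alone. Lipid droplet and uptake genes (18 members, camera adjusted p = 0.0643) and lipoprotein secretion genes (14 members, camera adjusted p = 0.921) had 0 members past either test.

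**Figure D3:**
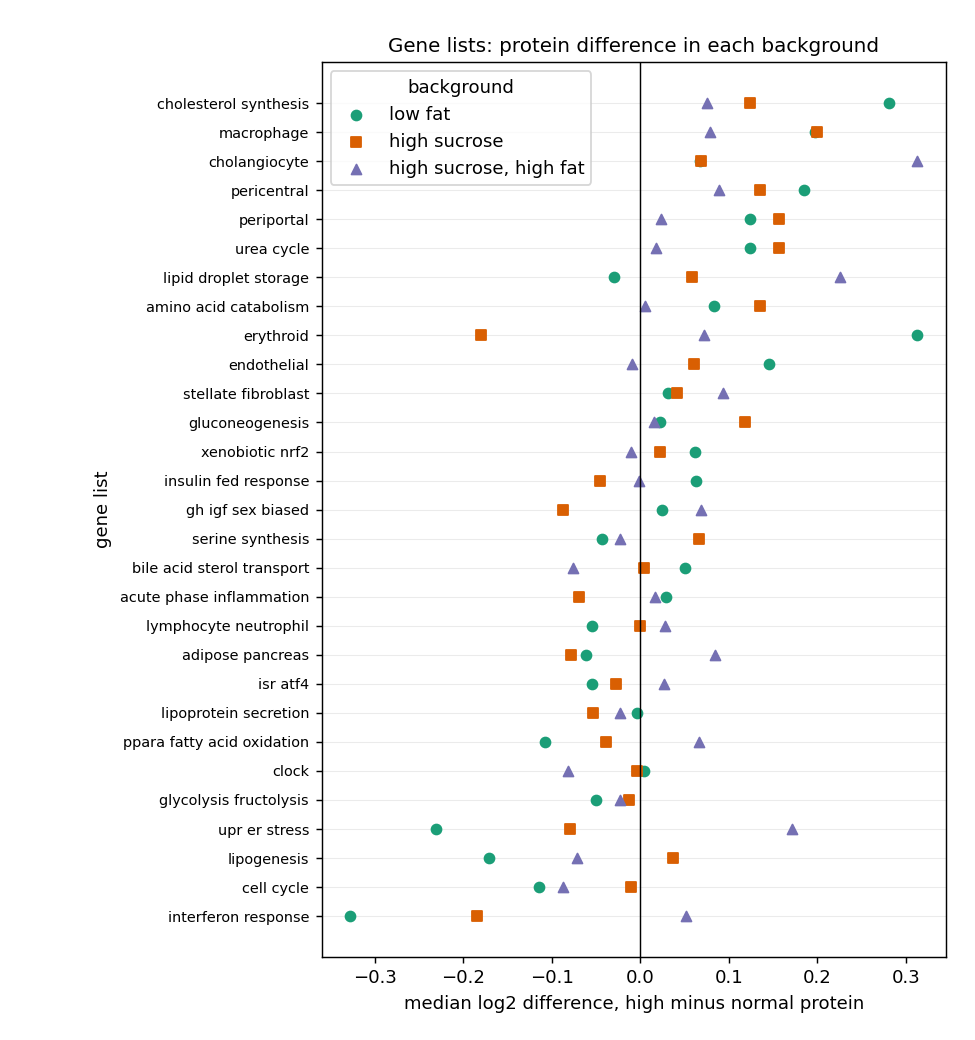
Median log2 difference, high protein minus normal protein (x axis), over the genes of each of 29 lists (y axis), with 1 point for each background. The cholesterol synthesis list stood at 0.28, 0.12 and 0.08 in the low fat, high sucrose and high sucrose high fat backgrounds, and the unfolded protein response list at -0.23, -0.08 and 0.17.

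Xenobiotic metabolism and NRF2 target genes went both ways (29 members, camera adjusted p = 0.579, median 0.05 and mean -0.01). Over the list alone Cyp2b2 (-0.97 ± 0.190 SE), Cyp2b1 (-0.33 ± 0.072 SE) and Aldh1a1 (-1.10 ± 0.217 SE) fell, and the heme oxygenase Hmox1 (0.46 ± 0.110 SE) and Cyp3a9 (0.28 ± 0.068 SE) rose. Of the integrated stress response targets (22 members, camera adjusted p = 0.772), Fgf21 and Nupr1 (-0.56 ± 0.102 SE) fell over the list alone; this list's median was 0.02 and its mean -0.03. Noct rose among the clock genes (1.24 ± 0.148 SE, 16 members, list camera adjusted p = 0.848), over the list alone. The acute phase protein Orm1 (0.38 ± 0.076 SE) and the cytokine inhibitor Socs3 (0.33 ± 0.068 SE) rose among the acute phase genes (27 members, list camera adjusted p = 0.848), each over the list alone. The unfolded protein response (camera adjusted p = 0.0784), growth hormone axis (0.718) and insulin and fed-state lists (0.422) had 0 members past either test. Cell division genes were lower (14 members, camera adjusted p = 0.0104, adjusted p = 0.699 with an estimated correlation), with the thymidylate synthase Tyms (-0.32 ± 0.066 SE) past the test over the list alone. Their median was -0.11 on low fat and -0.09 on high sucrose with high fat, and -0.01 on high sucrose, with 7 higher and 7 lower, inside the range of random lists. Interferon-stimulated genes were lower (22 members, camera adjusted p = 0.00298, adjusted p = 0.699 with an estimated correlation) with 0 members past either test. Their median was -0.33 on low fat, -0.18 on high sucrose and 0.05 on high sucrose with high fat, the last inside the range of random lists. On the NP array these genes lay above their mean over the arrays by a median of 0.34.

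Among the lists of markers of cell types other than hepatocytes, macrophage and bile duct markers passed camera for protein. Macrophage markers were higher (16 members, 14 with a fitted difference above 0, camera adjusted p = 4.76e-07, adjusted p = 0.699 with an estimated correlation). Cd5l was at 0.35 ± 0.082 SE and C1qc at 0.24 ± 0.071 SE, and 0 members passed either test. The median was 0.20 on low fat, 0.20 on high sucrose and 0.08 on high sucrose with high fat. Bile duct markers were higher (11 members, camera adjusted p = 0.00195, adjusted p = 0.699 with an estimated correlation), with 0 members past either test. Keratin 8, Krt8, which hepatocytes also make, was at 0.24 ± 0.075 SE, and its other tested probe set was at 0.1. The medians of the bile duct markers were 0.07, 0.07 and 0.31 in the same order, and the first 2 lay inside the range of random lists. Stellate cell markers (camera adjusted p = 0.0643), endothelial markers (0.0966), lymphocyte and neutrophil markers (0.932), red cell markers (0.286) and the adipose and pancreas markers that liver should lack (0.622) did not pass. Pericentral hepatocyte genes were higher (15 members, camera adjusted p = 5.42e-04, adjusted p = 0.699 with an estimated correlation). Slc1a4 (1.53 ± 0.248 SE), Slc1a2, Tbx3 (0.62 ± 0.094 SE), Oat and the ammonium transporter Rhbg (0.32 ± 0.074 SE) rose over the list alone, with list medians of 0.185, 0.135 and 0.089. Periportal hepatocyte genes were higher too (14 members, camera adjusted p = 0.0104, adjusted p = 0.699 with an estimated correlation). Hal, Sds, Pck1, Asl and the glutaminase Gls2 (0.27 ± 0.083 SE) rose over the list alone, and Hsd17b13 (-0.30 ± 0.098 SE) fell. Hal and Sds also count in the amino acid list, Pck1 and Sds in the gluconeogenesis list and Asl in the urea cycle list. Oat of the pericentral list counts in the amino acid list too, so these lists are not separate results. The periportal list had medians of 0.12 on low fat and 0.16 on high sucrose. On high sucrose with high fat its median was 0.02 (mean -0.006), inside the range of random lists. By fry, which tests whether a list's genes move on balance in 1 direction, 0 of the 29 lists passed for the protein effect (smallest adjusted p = 0.329). Fry found a simulated shifted list in 3 of 10.

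High sucrose against low fat at equal protein gave 0 probe sets past the limma test (lowest adjusted p = 0.464). An ordinary t statistic gave 0 too, which adds no evidence, because with 2 residual degrees of freedom it could hardly give a call. With the 4 arrays of the contrast alone, or without the NP-HS-HF or the HP-HS-HF array, 3 passed (lowest adjusted p = 0.00692), and without the NP-HS array 1. An unadjusted p under 0.05 was reached by 617 probe sets, where 1022 would be expected by chance. Named by rank and given as values, Vnn1 was at 0.36 ± 0.082 SE, the isopentenyl diphosphate isomerase Idi1 at 0.43 ± 0.111 SE, and the collagen cross-linking enzyme Lox at 0.91 ± 0.244 SE. On the lower side were the medium-chain acyl-CoA synthetase Acsm3 at -0.54 ± 0.107 SE and the homeobox factor Hhex at -0.57 ± 0.141 SE. The sucrose differences at normal and at high protein, which share no array, correlated across probe sets at r = -0.106 (Spearman -0.132). Differences of 1.5-fold or more numbered 177 at normal protein and 182 at high protein.

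By camera 4 lists differed with sucrose, and 0 members of any list passed over all genes or over the list alone. Interferon-stimulated genes were lower (adjusted p = 2.43e-06, adjusted p = 0.999 with an estimated correlation), with Usp18, which removes ISG15 from proteins, at -0.82 ± 0.288 SE and a list median of -0.39 at normal and -0.14 at high protein. Unfolded protein response genes were lower (adjusted p = 0.00482, adjusted p = 0.999 with an estimated correlation), with Sdf2l1 at -0.32 ± 0.198 SE; its median was -0.16 at normal and -0.04 at high protein, the latter inside the range of random lists, and without the NP array its mean was 0.03. Cholesterol synthesis genes were higher (adjusted p = 0.00145, adjusted p = 0.999 with an estimated correlation), with Tm7sf2 at 0.46 ± 0.144 SE. The median of that list was 0.17 at normal protein (17 higher, 5 lower), where the NP array enters, and -0.002 at high protein (11 higher, 11 lower). Macrophage markers were higher (adjusted p = 0.00145, adjusted p = 0.999 with an estimated correlation), with the galectin Lgals3 at 0.30 ± 0.082 SE and list medians of 0.08 at both protein levels, inside that range at normal protein. Without the NP array 1 list passed, and without the HP-HS array 2.

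High fat added to high sucrose gave 0 probe sets past the limma test (lowest adjusted p = 0.118), with 1013 at an unadjusted p under 0.05. An ordinary t statistic, which could hardly give a call, gave 0. Lpin1, the phosphatidate phosphatase lipin 1, fell by 0.78 ± 0.095 SE on the log2 scale over the lipogenesis list alone (2 protein levels). Acsm3 was at 0.91 ± 0.107 SE, the secreted stanniocalcin Stc1 at 0.92 ± 0.135 SE, the ephrin receptor Epha2 at 0.56 ± 0.088 SE, the estrogen receptor Esr1 at -0.42 ± 0.092 SE and the transcription factor Foxo3 at -0.37 ± 0.080 SE, none of them past the test. Differences of 1.5-fold or more numbered 191 at normal and 260 at high protein, and the differences at the 2 protein levels correlated across probe sets at r = 0.057 (Spearman 0.049). Without the NP-HS-HF array the count past the test was 17.

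By camera 5 lists differed with fat. Lipogenesis genes were lower (adjusted p = 0.00841, adjusted p = 0.825 with an estimated correlation), with Lpin1 as the 1 member of 24 past the test over the list alone and Scd at -0.60 ± 0.213 SE. The list's median was -0.008 at normal protein (11 higher, 13 lower), inside the range of random lists, and -0.14 at high protein (5 higher, 19 lower). Pericentral genes were higher (adjusted p = 0.0138, adjusted p = 0.825 with an estimated correlation), and Slc1a2 (0.41 ± 0.117 SE), Tbx3 (0.47 ± 0.115 SE), Rhbg (0.37 ± 0.090 SE) and Lect2 (0.30 ± 0.078 SE) rose over the list alone, with list medians of 0.09 at normal and 0.05 at high protein, the latter inside that range. Interferon-stimulated genes were lower (adjusted p = 2.59e-04, adjusted p = 0.968 with an estimated correlation), with Oas1b at -0.50 ± 0.176 SE. Their median was -0.28 at normal protein (1 higher, 21 lower) and -0.07 at high protein (8 higher, 14 lower), where the mean, -0.04, lay inside the random range. Macrophage markers were lower (adjusted p = 2.97e-04, adjusted p = 0.825 with an estimated correlation), with Gpnmb at -0.43 ± 0.149 SE, 12 of 16 members below 0 in the fit, and medians of -0.17 at normal and -0.20 at high protein. Stellate cell markers were higher (adjusted p = 0.00727, adjusted p = 0.825 with an estimated correlation), with the platelet-derived growth factor receptor Pdgfrb at 0.29 ± 0.080 SE; their medians, 0.07 and 0.04, lay inside the range of random lists at each protein level. Without the NP-HS array 8 lists passed.

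High sucrose with high fat against low fat, at equal protein, gave 0 probe sets past the limma test (lowest adjusted p = 0.2), with 1059 at an unadjusted p under 0.05. An ordinary t statistic, which could hardly give a call, gave 0. Over their lists alone Lpin1 (-0.72 ± 0.095 SE), Pklr (-0.40 ± 0.078 SE), the fructose transporter Slc2a5 (-0.44 ± 0.106 SE) and the glucuronosyltransferase Ugt2b1 (-0.53 ± 0.086 SE) fell. The insulin-repressed binding protein Igfbp1 (0.60 ± 0.095 SE) and Idi1 (0.61 ± 0.111 SE) rose. As values, Lox was at 1.85 ± 0.244 SE, the small heat shock protein Hspb1 at 1.13 ± 0.219 SE, the ephrin Efna1 at 0.79 ± 0.114 SE, its receptor Epha2 at 0.59 ± 0.088 SE, and Esr1 at -0.54 ± 0.092 SE. Differences of 1.5-fold or more numbered 237 at normal protein and 243 at high protein, and the 2 sets correlated across probe sets at r = 0.005 (Spearman -0.053). Without the NP-HS-HF array the count past the test was 12, and without the HP-HS-HF array it was 1.

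By camera 6 lists differed with sucrose and fat together. Interferon-stimulated genes were lower (22 members, 21 below 0 in the fit, adjusted p = 2.58e-14, adjusted p = 0.888 with an estimated correlation). Usp18 (-1.35 ± 0.288 SE), Oas1b (-0.84 ± 0.176 SE), the regulator Irf7 (-0.84 ± 0.212 SE), Oasl (-0.60 ± 0.095 SE), Herc6 and Ifit3 fell over the list alone. The median of the list was -0.56 at normal and -0.15 at high protein, and the NP array enters the former. Lipogenesis was lower (adjusted p = 0.00317, adjusted p = 0.888 with an estimated correlation), at medians of -0.12 at normal and -0.08 at high protein, the latter inside the range of random lists. Cholesterol synthesis was higher (adjusted p = 8.53e-06, adjusted p = 0.888 with an estimated correlation). The cholesterol list's median was 0.20 at normal protein (21 higher, 1 lower), with the NP array in the difference, and 0.03 at high protein (12 higher, 10 lower), inside the range of random lists. Pericentral genes were higher (adjusted p = 0.00196, adjusted p = 0.888 with an estimated correlation), with Tbx3 (0.65 ± 0.115 SE), Slc1a2 (0.44 ± 0.117 SE), Rhbg (0.42 ± 0.090 SE) and Lect2 (0.29 ± 0.078 SE) past the test over the list alone. Their median was 0.12 at normal protein (14 higher, 1 lower), where the NP array enters, and 0.007 at high protein (8 higher, 7 lower), inside the random range. Stellate cell markers were higher (adjusted p = 0.00196, adjusted p = 0.888 with an estimated correlation), with the pericyte marker Rgs5 (0.47 ± 0.097 SE) past it and medians of 0.10 at normal, inside the random range, and 0.14 at high protein. The unfolded protein response list was lower (adjusted p = 0.00317, adjusted p = 0.915 with an estimated correlation), at a median of -0.26 at normal and 0.06 at high protein, and its mean was 0.01 without the NP array and 0.05 without the NP-HS-HF array. Without the NP array 2 lists passed.

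**Figure D4:**
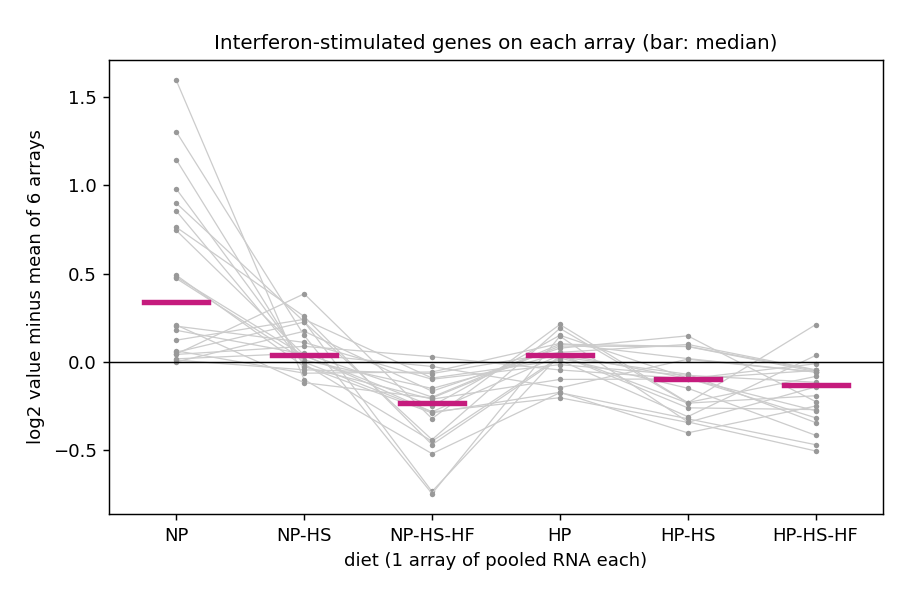
Log2 value minus the mean over the 6 arrays (y axis) of 22 interferon-stimulated genes on each diet's array (x axis); each grey point is a gene, grey lines join the values of a gene, and the pink bar is the median. The median was 0.34 on the NP array and -0.23 on the NP-HS-HF array, and between -0.13 and 0.04 on the other arrays.

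The correlation of the protein effect with the sucrose and fat effect across probe sets was r = 0.13 (Spearman 0.096). For the protein difference on high sucrose against NP-HS-HF minus NP, which share no array, it was r = -0.004 (Spearman -0.048). Neither value can decide whether genes that differed with sucrose and fat differed the other way with protein. The sucrose and fat differences at normal and at high protein correlated across probe sets at r = 0.005 (Spearman -0.053). For sucrose and fat 0 probe sets passed the test, which missed most of the smallest simulated changes. The count of 0 therefore does not show that there was no response, and it leaves no called genes to set against protein. Most interferon-stimulated genes were lower with sucrose and fat at both protein levels. At normal protein, where the NP array enters, 0 were higher and 22 lower, and at high protein 6 were higher and 16 lower. Lpin1, with the largest fall of the lipogenesis list for sucrose and fat, had protein differences of -0.19, 0.08 and -0.08 in the 3 backgrounds, while Pklr was lower in both comparisons. Tbx3, Slc1a2 and Rhbg were higher with high protein and with sucrose and fat, each over the pericentral list alone.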

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

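The tests of the interferon, macrophage and concordance patterns and of other splits of the arrays were chosen after the results were seen. Each other result in this part is a difference between levels of the other factor in which the values went opposite ways, for lists with both medians outside the central range of random lists. These contrasts have 1 array on each side, so none of the differences between them was tested.

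The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05; the real split gave 9 genes past the test, as many as 1 of the 10 splits (itself), and the highest other gave 1. For gene lists the real split gave 11 past camera, 3 of the 10 splits gave as many, the real one included, and the highest other gave 12. Of the other 9 splits, 6 part the arrays of 1 background alone, the splits with 12 lists among them, and so rest on 1 pair of arrays; the 3 that part all 3 backgrounds, as the real one does, gave 0 genes each and 10, 5 and 0 lists. The 227 probe sets concordant over the 3 backgrounds are more than the 89.8 that unrelated differences would give on average, the mean of the 4 patterns of signs, and the highest with a sign turned was 53, but 4 patterns are too few for a share under 0.05. A technical difference shared by the 3 high protein arrays could give the same count as an effect of protein, and the labels name no batch with which to test it.

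Interferon-stimulated genes were highest on the NP array, by a mean of 0.58 ± 0.123 SE over 22 genes against the other 5 arrays, with 21 of them higher. More macrophages in that pool than in the other 5 on average is argued against, since their markers were lower there, with a mean difference of -0.147 ± 0.041 SE over 16 genes. That SE is over genes of 1 pool, and the other arrays include those of high protein, where these markers were higher. Their median deviation was -0.094 on the NP array, -0.006 on NP-HS and -0.135 on NP-HS-HF, so they were not lower than on NP-HS-HF. More lymphocytes or neutrophils stays open, with 0.025 ± 0.042 SE over 9 genes that went both ways. Scaling of the array as the whole cause is argued against: other genes of like mean expression stood at -0.003 (SD 0.030 over 10000 random lists), though normalisation between arrays holds such averages near 0, and macrophage markers went down on the same array. A single deviating NP pool cannot be told apart from an effect of diet. The HP-HS-HF minus HP difference of the list, which leaves the NP array out, was -0.188 ± 0.042 SE over genes, but these genes move together and 1 deviating HP pool could give it as well.

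Macrophage markers were higher with high protein by a mean of 0.17 ± 0.051 SD over 3 backgrounds, and lower with fat, at -0.135 ± 0.064 SD over 2 protein levels. A lower share of hepatocytes in the high protein pools would raise the markers of every other cell type alike. The other types stood at 0.07 ± 0.038 SD, and the difference of 0.105 ± 0.089 SD is under 2 SD, so this cannot be told apart from more macrophages. For fat, the macrophage markers went down and the others up (0.06 ± 0.045 SD), a difference of -0.193 ± 0.109 SD. A changed share of hepatocytes alone would move both the same way. Stellate and endothelial markers rose at both protein levels. Bile duct and lymphocyte and neutrophil markers fell at normal protein (means -0.043 and -0.033) and rose at high protein (0.128 and 0.022). With 2 protein levels the difference stays under 2 SD, so a changed share of hepatocytes is not excluded.

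The erythroid marker median of the protein difference was 0.31 on low fat and -0.18 on high sucrose, a difference of -0.493. Its sucrose difference was 0.19 at normal and -0.27 at high protein, a difference of -0.461. Gene by gene this is the same contrast of the same arrays, and only the use of medians makes the values differ. The unfolded protein response median of the protein difference went from -0.23 on low fat to 0.17 on high sucrose high fat, a difference of 0.402. With fat, the unfolded protein response list stood at -0.14 at normal and 0.11 at high protein, a difference of 0.253. With sucrose and fat it stood at -0.26 and 0.06, a difference of 0.319, which restates the contrast that gave 0.402. PPAR alpha targets went from -0.11 to 0.07 in the protein difference, between low fat and high sucrose high fat, a difference of 0.174. With sucrose and fat they differed by 0.111 between protein levels, which is again the same contrast gene by gene. Lipogenesis genes with sucrose differed by 0.108 between protein levels, from -0.05 to 0.06, and gluconeogenesis genes by 0.081, from -0.04 to 0.04. Amino acid breakdown genes with fat went from 0.07 to -0.07, a difference of -0.138. Lipid droplet genes with sucrose and fat went from -0.06 at normal to 0.15 at high protein, a difference of 0.209.

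Among single genes, Ly6al had protein differences of -1.40 on low fat and -1.41 on high sucrose against 0.65 on high sucrose high fat, each 2.06 apart. Its fat differences, -0.81 at normal and 1.25 at high protein, were 2.06 apart as well, which restates the contrast between the high sucrose backgrounds. Hamp, the gene of hepcidin, was at 0.69 with sucrose at normal protein and -2.27 at high protein, a difference of -2.96. The cytokine signalling inhibitors Socs2 and Cish, both targets of growth hormone signalling, had fat differences of -1.18 and -1.15 at normal protein and 1.18 and 1.06 at high protein, which are 2.37 and 2.20 apart. The same 4 arrays gave the same 2.37 and 2.20 between the protein differences of the high sucrose backgrounds. Slc25a30 with sucrose and fat was at -0.72 and 1.58, a difference of 2.30. Tmod1, a red cell tropomodulin, was at 0.67 and -0.94 with sucrose, a difference of -1.61, and differed by -1.51 with sucrose and fat. Gpm6a was at 0.88 and -0.99 with sucrose and fat, a difference of -1.87, which is also that of its protein differences on low fat and high sucrose high fat. The quinone reductase Nqo1 was at 0.68 and -0.74 with sucrose, a difference of -1.42, and the protease inhibitor A2m at 0.69 and -0.78, a difference of -1.47.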

How the results depend on the processing

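Testing named genes alone and counting concordance over the high sucrose backgrounds alone were chosen after seeing the data; the other alternatives were planned. The 9 genes past the test for protein numbered 3 with no filter (all 3 among the 9), 57 with a trend and robust prior, 0 with an ordinary t statistic, 41 at an adjusted p under 0.10, 528 at an unadjusted p under 0.01, 59 with named genes only and 17 with array weights. The 57, 41, 59 and 17 held all 9. The 0 with an ordinary t statistic came from a test with 2 residual degrees of freedom, which could hardly give a call. Cyclic loess and a repeated quantile normalization gave 7 each, all among the 9. A filter at the 50th percentile gave 13, which held all 9. With no background term there were 13, of which 6 were shared. They numbered 0 without the low fat background, 0 without the high sucrose background and 48, with all 9 among them, without the high sucrose high fat background. Leaving out 1 array gave 0 to 48, and leaves its partner with no weight in the protein effect, so it equals leaving out the background: 0 without the NP, HP, NP-HS or HP-HS array and 48 without the NP-HS-HF or HP-HS-HF array. Such fits have 1 residual degree of freedom and assume that a lone array varies like the others.

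The counts of 0 became 114, 230 and 233 at an unadjusted p under 0.01 for sucrose, fat, and sucrose with fat. For sucrose, the 4 arrays of the contrast alone gave 3, and leaving out 1 array gave 0 to 3, with 1 without NP-HS and 3 without NP-HS-HF or HP-HS-HF. For fat, leaving out 1 array gave 0 to 17 (17 without NP-HS-HF), and for sucrose with fat 0 to 12 (12 without NP-HS-HF, 1 without HP-HS-HF). The cause was not tested.

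Concordant probe sets numbered 842 at 1.1-fold, 33 at 1.5-fold, and 620 over the high sucrose backgrounds alone, against 187 there with 1 sign turned. The correlation of the protein effect with the sucrose and fat effect was 0.062 with no filter and 0.178 above the 50th percentile; the cause was not tested. Protein differences between 2 arrays on low fat, high sucrose and high sucrose high fat numbered 2539, 2439 and 2982 at 1.2-fold, 42, 58 and 52 at 2-fold, and 478, 449 and 489 with no filter, and 201 on high sucrose high fat above the 50th percentile. Diet differences, in the order sucrose, fat, sucrose with fat, at normal and then high protein each, numbered 1951, 1847, 1986, 2309, 2397 and 2439 at 1.2-fold, 28, 27, 21, 45, 34 and 36 at 2-fold, 337, 359, 390, 427, 413 and 434 with no filter, and 108, 97, 97, 162, 150 and 135 above the 50th percentile. A fold threshold or filter that is looser or stricter changes these counts by construction.

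The lists past camera, 11, 4, 5 and 6 for protein, sucrose, fat, and sucrose with fat, became 0 in each effect with an estimated correlation and 0 in each by fry. These 2 tests found a simulated shifted list in 0 and 3 of 10, so their counts of 0 cannot decide whether a list differed. Camera with the preset correlation cannot decide it either where genes of a list vary together. Leaving out 1 array gave 7 to 11 for protein (7 without NP or HP), 1 to 5 for sucrose (1 without NP, 2 without HP-HS), 4 to 8 for fat (8 without NP-HS) and 2 to 9 for sucrose with fat (2 without NP). The mean of the unfolded protein response list for sucrose, -0.109, ranged from -0.245 without HP to 0.026 without NP. For sucrose with fat it was -0.124 and ranged from -0.295 without HP-HS-HF to 0.047 without NP-HS-HF, with 0.012 without NP. Lists outside the random range by the mean of members, not the median, numbered 15 for fat at normal protein and 14 for sucrose with fat at high protein. The settings other than leaving out 1 array gave 917 values of named genes. They include settings that leave out a background or keep only the 4 arrays of a contrast. Of the 917, 829 kept their direction and side of the threshold, 40 fell below it, 48 came past it and 0 turned. With 1 array left out, 36 of 576 fell below and 18 came past it. These genes were chosen for 1 direction at every level of the other factor, which favours 0 turns. All but the 9 past the test for protein were below the threshold at the outset. Of 825 values of list members under the same settings, 651 kept their direction and side and 174 fell below. With 1 array left out, 227 of 492 fell below. Of 156 values of lists with 1 array left out, 41 fell below and 3 turned.

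The arrays are paired by background in the fit used for the protein effect, and the fit with no background term is the one without pairs. The labels carry no replicate numbers, so no other pairing was run. Detection calls are not used here, so signal over background was judged by the filter alone.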

Other observations

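The tests of 3 lists of target genes were set before the lists' values were seen, although Fkbp5 of the glucocorticoid list had been seen by then and 3, 6 and 3 of the members of the cAMP, ChREBP and glucocorticoid lists also sit in the earlier lists.

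Genes named for large fat differences at 1 protein level mostly differed less at the other, as such a choice favours, so no dependence on protein is read from them. Among those named at normal protein, Gpm6a was at 0.91 there and -0.35 at high protein, and Ubd at 0.91 and -0.04. Among those named at high protein, Pdk4, the kinase that shuts off pyruvate dehydrogenase, was at 0.59 with fat at normal protein and 1.76 at high protein (fitted fat effect 1.17 ± 0.299 SE, adjusted p = 0.113 over the list alone). Angptl4, an inhibitor of lipoprotein lipase, had a fitted fat effect of 0.66 ± 0.168 SE. Egln3, an oxygen-sensing prolyl hydroxylase, was at 0.20 and 1.52, and Fkbp5, a glucocorticoid-induced chaperone partner, at -0.27 and -1.08. Scd was at -0.12 and -1.09. Among clock genes, Bmal1 was at 0.59 ± 0.129 SE and Per1 at -0.38 ± 0.112 SE with sucrose and fat, with adjusted p of 0.0526 and 0.0887 over the list alone.

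A hypothesis is that glucagon and cAMP signalling was stronger with high protein, in which case the targets would be higher. The mean of 15 such genes was 0.139 ± 0.036 SD over 3 backgrounds, at percentiles 99.6, 97.9 and 99.9 of matched random lists, as was set for the mean of the list, but 3 of the members were higher in all 3 backgrounds (0 lower) and the others were not of 1 direction. Fos (0.47) and Pde4b (0.53) lead the list, and without these the mean was 0.083. Camera gave p = 1.99e-04, and p = 0.0579 with an estimated correlation. Fos also responds to many other stimuli, so the source of the signal may lie elsewhere.

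Another hypothesis is a weaker carbohydrate response through ChREBP with high protein. The mean of 14 target genes was -0.118 ± 0.128 SD, at percentiles 0, 21.4 and 36.2, so the mean stood apart on low fat and not on the other backgrounds. Of the members, 6 were lower in all 3 backgrounds and 0 were higher in all 3. Camera gave p = 0.0021, and p = 0.312 with an estimated correlation. The hypothesis stays open. Stronger glucocorticoid signalling with high protein stays open as well. The mean of 12 targets was 0.05 ± 0.155 SD, with 0.11 on low fat, 0.17 on high sucrose and -0.13 on high sucrose high fat, and Mt1 (0.48) and Fkbp5 (0.12) moved unlike each other across backgrounds.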
